A study of Homo sapiens with 2 samples.

How the data were processed

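Gene expression was measured in KYSE510 cells, a human oesophageal squamous cell carcinoma line, on 2 Agilent 1-colour (Cy3) whole-genome arrays. One array held RNA from control cells and the other RNA from cells kept for 24 h with 100 nM of a compound that the labels name only as PAF. The labels give 1 array per group, so there were no replicates, and the precision is limited by the number of arrays. Per the file headers, both arrays lay on the same slide and were scanned in the same session, so neither slide nor scan separates the groups, but the place on the slide cannot be told apart from the group. What the control cells received in place of PAF is not given in the sources used here.

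The deposited scanner files hold spot intensity values on a linear scale, made by the authors with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. Per the file headers, the processed signal was corrected for local background and for trends across the array, and spots not above background received a substitute signal. Other columns of the deposited files hold the raw intensity of each spot and its background, and flags for spots well above background, saturated spots and outliers. The deposited series table holds linear intensity values that equalled the mean processed signal of each probe's spots, within a relative tolerance of 0.001, for 99.9% of the probes of each array. Its column medians were 18.3 for the control array and 16.5 for the PAF array, so it had not been centred between arrays.

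Each array carried 60901 spots other than controls, for 58201 probes. On the control array 54.1% of these spots were well above background, and on the PAF array 55.4%. None was saturated, and 61 and 98 spots were flagged as outliers. From these files, the log2 of the processed signal was taken, and the 75th percentile of each array over its spots other than controls was subtracted (348 on the control array and 322 on the PAF array before the log). Outlier spots were left out, and spots of one probe were averaged. A gene took the value of its brightest probe by the mean of both arrays, among probes well above background on both. The log2 difference is the PAF value minus the control value, and folds are 2 to the power of its size. A gene whose probes were well above background on only the PAF or only the control array has a bound, written "at least N-fold": its value was set against the lowest signal well above background on the dimmer array, or against its own signal there if higher.

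Gene names were updated through the reference RefSeq table, which held the accessions of 31104 probes. A further 396 probes were renamed through a unique synonym, and other probes kept the file's name. In all, 30717 probes carried a gene symbol, for 20979 genes, and 27484 probes carried none and were counted apart. Probe coordinates are those of the files, on hg19. Of 14821 genes well above background on both arrays, 4457 had several such probes. The pooled SD of the difference between probes of one gene was 0.38, with a median SD of 0.17. In RRP12, SEC14L1 and TUBB8, the 3 genes concerned, some probes were at least 2-fold higher and others at least 2-fold lower. Over 283 probes with at least 8 usable spots, the median SD between spots of one probe was 0.036 on each array. The spread between spots is technical. That between probes of a gene can also hold differences between the transcripts that they read. Neither measures the spread between cultures treated alike.

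No test of the treatment could be made with 1 array per group, and no p-value or SE was computed across genes, which are not replicates. Genes at least 2-fold and at least 4-fold apart were counted. For 45 gene lists, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list is said to stand apart when its median lies below the 2.5th or above the 97.5th percentile, which describes these 2 arrays. For 45 lists of randomly drawn genes, 2.25 would do so by chance. Genes of 1 pathway can vary together and some lists share members. The number expected for these lists between 2 cultures treated alike is therefore not known. The lists include markers of fibroblasts, leukocytes, endothelium and blood. The lists, thresholds and the rule for naming genes were set before the data were examined. The rule took, among genes brighter than the median, the 8 with the largest difference each way. Among dimmer genes it took 3 each way, and among genes with a bound 3 each way. In each list described it took up to 4 members with the largest difference. Some genes that the rule took are not given here. Other members named as exceptions to a count, and the PAF receptor gene, were chosen outside that rule, the exceptions after their values were seen.

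The counting was tested on simulated data made from these 2 arrays, with noise of the size seen between probes of one gene. In a step on 14821 genes, 94.0% of 100 genes given a 3-fold difference were counted as at least 2-fold apart, as were 100.0% of 100 genes given a 6-fold difference. Of the 14621 genes left alone, 1.02% were counted. The list step was run on the real differences. Of 100 random lists of 20 genes, 5 stood apart, as did all 20 such lists with 0.8 added to each difference. These lists came from the same genes as the comparison lists, so the first result was set by the method. It says nothing about lists of genes that vary together. The simulated noise holds no spread between cultures treated alike, so the tests say nothing about differences between cultures.

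The alternatives were quantile normalization, centring on the 75th percentile of probes well above background, loess between the arrays, normexp background correction with an offset of 50, and the authors' deposited table. Others were no filter on dim probes, only genes brighter than the median, the mean over a gene's probes, outlier spots kept and saturated probes left out. Random lists were also drawn without matching, and a looser flag for signal above background was tried. Centring on spike-in RNAs and on the gene median were added after seeing the data. Calculations used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.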

Results

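The expression of 14821 genes was measured above background in both KYSE510 cultures, one the control and one kept for 24 h with 100 nM PAF. The comparison addressed which genes respond to PAF in these oesophageal squamous carcinoma cells. With 1 array per group, none of the differences given here has a replicate check, and no p-values are given. Of the spots other than controls, 54.1% were well above background on the control array and 55.4% on the PAF array. Values are log2 differences, PAF minus control, or the corresponding folds.

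On the PAF array, genes of squamous differentiation, of the response to low oxygen and of inflammatory signalling had higher signals. Genes of DNA replication, mitosis and ribosome assembly had lower signals. The hypoxia list had a median difference of 2.28 (4.84-fold), and the squamous differentiation list one of 1.65 (3.14-fold). The S phase list had a median of -1.69 (3.23-fold lower), and the ribosome biogenesis list one of -1.45 (2.73-fold lower). In all, 1445 genes (9.75%) were at least 2-fold higher and 1714 (11.6%) at least 2-fold lower. At the 4-fold threshold there were 412 higher and 128 lower genes. Across genes the arrays correlated at r = 0.951, genes not being independent replicates, and 56.0% of genes differed by less than 1.5-fold.

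The median difference of all genes was -0.12. It became 0.04 with centring on probes well above background, -0.29 with centring on spike-in RNAs and 0.00 with centring on the gene median. Of the genes at least 2-fold apart, 45.7% were higher on the PAF array, against 60.5%, 31.0% and 56.5% under those centrings. Which direction holds more genes at 2-fold therefore depended on the scaling. Genes lower by 4-fold ranged from 54 with normexp to 267 with no filter on dim probes.

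**Figure D1:**
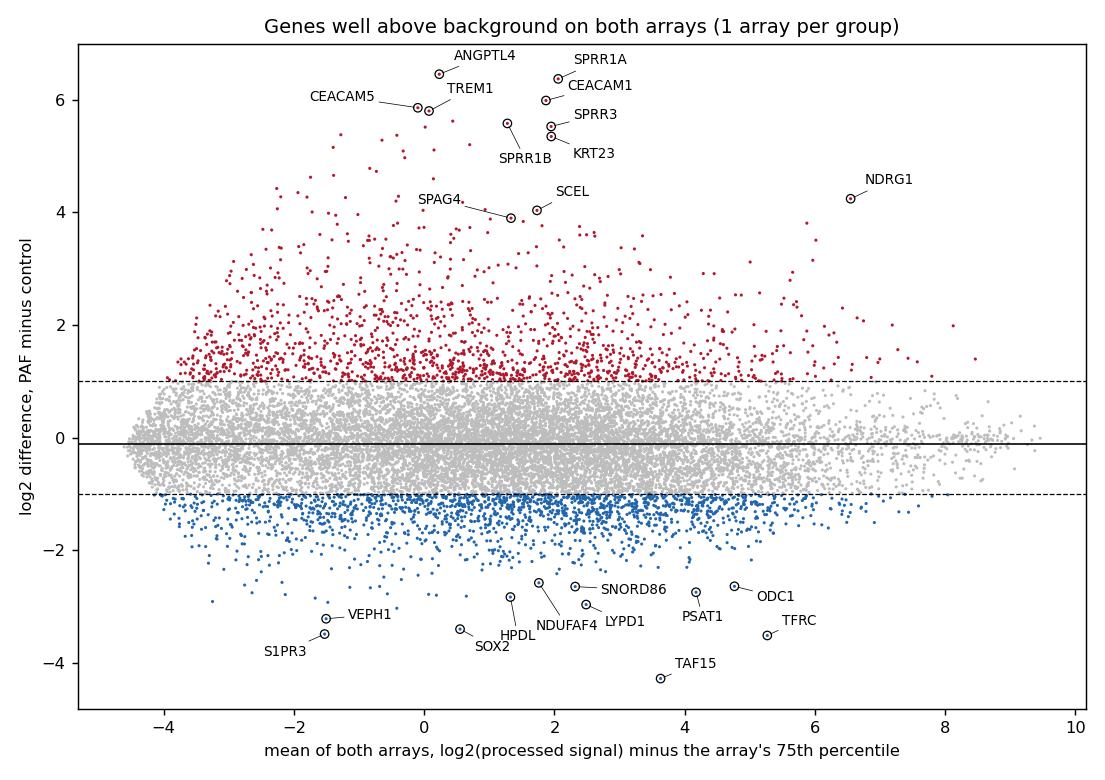
Each point is 1 of 14821 genes, with the mean log2 signal of both arrays relative to the 75th percentile on the x axis and the log2 difference, PAF minus control, on the y axis. The dashed lines mark 2-fold (1445 genes in red higher, 1714 in blue lower), the solid line marks the median of -0.12, and circled genes are those named by size of difference.

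Among genes brighter than the median, the 8 with the largest excess on the PAF array included 4 of the cornified envelope of squamous epithelium, SPRR1A, SPRR1B, SPRR3 and SCEL. SPRR1A, a precursor of the cornified envelope, had a processed signal of 159 in the control and 12206 with PAF, an 82.8-fold difference at its probe on chromosome 1 (152958192 to 152958251, hg19). The mean over its probes was 4.69, against 6.37 for the brighter one. SPRR1B was 47.8-fold higher and SPRR3 46.1-fold higher. CEACAM1, a cell adhesion molecule of the immunoglobulin superfamily, was 63.4-fold higher (chromosome 19, 43011504 to 43011563). The keratin gene KRT23 was 40.7-fold higher, SCEL, which encodes the envelope protein sciellin, 16.4-fold and SPAG4 14.9-fold. NDRG1, a known hypoxia-responsive gene, had a signal of 7492 in the control and 131174 with PAF, 18.9-fold higher (chromosome 8, 134249719 to 134249778). Among dimmer genes, ANGPTL4, a secreted regulator of lipoprotein lipase, was 87.7-fold higher, CEACAM5 58.0-fold and the myeloid receptor gene TREM1 55.8-fold.

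The lower genes of the brighter group were led by TAF15, an RNA-binding protein gene. Its signal was 19011 in the control and 905 with PAF, 19.4-fold lower, from 1 probe with 1 spot (chromosome 17, 34173994 to 34174053). TFRC, the transferrin receptor, was 11.4-fold lower from a probe with 10 spots (chromosome 3, 195776593 to 195776652). LYPD1 was 7.82-fold lower, HPDL 7.13-fold and NDUFAF4, an assembly factor of respiratory complex I, 5.98-fold. PSAT1, of serine synthesis, was 6.72-fold lower, ODC1, the first enzyme of polyamine synthesis, 6.24-fold and the small nucleolar RNA SNORD86 6.26-fold. Among dimmer genes, the sphingosine-1-phosphate receptor gene S1PR3 was 11.2-fold lower and SOX2, a transcription factor of squamous progenitors, 10.6-fold lower. VEPH1 was 9.31-fold lower, and its other probe gave -1.87 against -3.22. All of these genes except TFRC rested on 1 spot per probe. Not all probes of some genes were well above background on both arrays. Only 1 of 4 was for S1PR3, 1 of 3 for TREM1, 1 of 2 for CEACAM1 and 2 of 3 for LYPD1. With normexp background correction, which shrinks the differences of dim genes, the log2 difference of ANGPTL4 was 5.21 against 6.45, that of TREM1 4.65 against 5.80 and that of S1PR3 -2.16 against -3.49. It was 4.64 against 5.86 for CEACAM5, 4.91 against 5.58 for SPRR1B and -1.997 against -3.22 for VEPH1.

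Some genes were well above background on one array alone. The PAF array alone gave 658 such genes, 178 of them with a bound of at least 2-fold, and the control array alone gave 392, of which 71 had such a bound. By probes the numbers were 2399 and 1634. SMIM5 was at least 80.0-fold higher on the PAF array. The nuclear receptor gene RORA was at least 24.9-fold higher there. On the control array, CYP26A1, a retinoic acid hydroxylase, was at least 11.7-fold higher, SPDYE1 at least 8.30-fold and the phosphatase gene DUSP2 at least 7.72-fold.

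Of the 45 gene lists, 17 stood apart as higher and 7 as lower, and 21 did neither. For lists of randomly drawn genes 2.25 would be expected, a number that does not hold for genes that vary together.

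**Figure D2:**
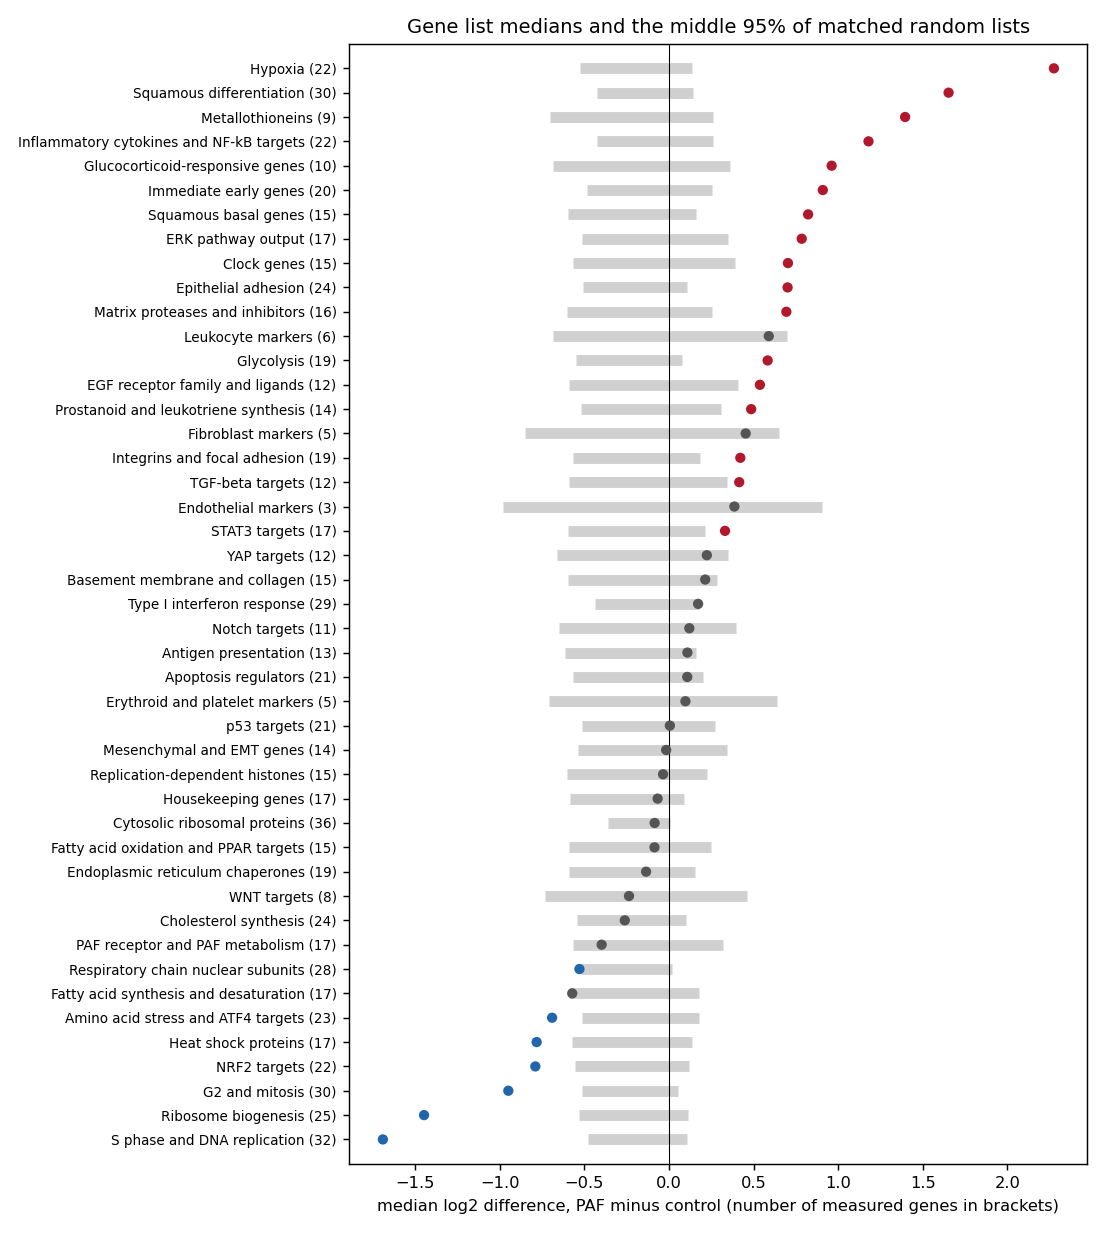
Points are the median log2 differences, PAF minus control, of the measured genes of 45 lists (red higher, blue lower, grey neither), and bars span the range of 10000 random lists matched on signal outside which a list stands apart. The hypoxia list lies farthest right at 2.28 and the S phase list farthest left at -1.69.

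All 22 hypoxia genes had higher signals on the PAF array (21 with centring on spike-ins, where BNIP3L fell below 0), 20 of them by at least 2-fold, and the list's median lay above that of all 10000 random lists. After ANGPTL4 and NDRG1, the largest differences were those of LOX, a collagen cross-linking enzyme (14.3-fold), and ANKRD37 (11.4-fold). BNIP3L (1.11-fold) and PLOD2 (1.89-fold) stayed under 2-fold. The glycolysis list had a median of 0.58, with 15 of 19 genes above 0 and 5 at least 2-fold higher. ENO2 was 5.66-fold, the lactate transporter gene SLC16A3 3.81-fold, ALDOC 3.68-fold and HK2 3.66-fold higher, while PFKM was 2.27-fold lower. The respiratory chain list had a median of -0.53, with 27 of 28 subunits below 0. CYC1 was 2.39-fold lower. This list lay at the 2.25th percentile and no longer stood apart under 6 of the alternatives.

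Of 30 measured squamous differentiation genes, 27 were above 0 (25 to 28 over the scalings) and 23 at least 2-fold higher. Beside the SPRR genes, S100A9, a subunit of calprotectin, was 16.6-fold higher. The genes below 0 were FLG (-0.67), KRT10 (-0.24) and KRT4 (-0.09). The squamous basal list also stood apart as higher, with a median of 0.82. In that list 12 of 15 genes were above 0, with KRT17 5.56-fold, KRT14 5.33-fold and COL17A1 5.32-fold higher. The 3 genes below 0 included SOX2 and KRT5 (-0.32). The epithelial adhesion list had a median of 0.70, with 19 of 24 genes above 0 and 7 at least 2-fold higher. Among its largest differences were those of MUC1 (8.68-fold, or a log2 difference of 2.49 as the mean over its probes), OVOL1 (2.88-fold) and CLDN4 (2.65-fold). The mesenchymal list did not stand apart, at a median of -0.02 whose sign changed with the scaling. Within it LOX was 14.3-fold higher, CDH2, the gene of N-cadherin, 4.34-fold lower, TGFB1 3.40-fold higher and TWIST1 2.85-fold lower. With normexp the difference of TWIST1 was -0.34, under 2-fold. Another 5 of its members were above background on the PAF array alone, including VIM (at least 3.89-fold) and ZEB2 (at least 3.43-fold).

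Inflammatory genes and NF-kB targets had a median of 1.18, with 19 of 22 measured genes above 0 and 14 at least 2-fold higher. PTGS2, the inducible cyclooxygenase, was 21.5-fold higher, IRAK2 9.44-fold, TNFAIP3 5.39-fold and SAA2 4.90-fold. With normexp the log2 difference of PTGS2 was 2.47 against 4.42, and that of IRAK2 2.52 against 3.24. The median was 1.09 with the 3 members at their bound included. IL6, TNF and CCL2 were not well above background on either array. The prostanoid and leukotriene list stood apart as higher (0.49). In that list HPGD was 4.43-fold and ALOX5 2.79-fold higher, and PTGES2 3.24-fold lower. It did not stand apart among genes brighter than the median, where its median was 0.23, and HPGD was under 2-fold with normexp (0.77). The STAT3 target list had a median of 0.33, with OSMR 7.43-fold (a log2 difference of 1.84 as the mean over its probes) and PIM1 5.03-fold higher, and FGL1 3.37-fold and BIRC5 2.27-fold lower.

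Immediate early genes had a median of 0.91, with 18 of 20 above 0 and 9 at least 2-fold higher. FOS was 10.1-fold, KLF2 7.15-fold, NR4A2 3.85-fold and JUN 3.62-fold higher. With normexp the log2 difference was 2.74 against 3.34 for FOS, 1.39 against 2.84 for KLF2 and 0.98, just under 2-fold, for NR4A2. The list of ERK pathway output had a median of 0.78. Its largest differences were those of the phosphatase genes DUSP6 (9.26-fold), DUSP5 (7.47-fold) and DUSP4 (4.44-fold) and of ETV4 (4.19-fold). With normexp the log2 difference was 2.43 against 3.21 for DUSP6, 2.26 against 2.90 for DUSP5 and 1.04 against 2.07 for ETV4. Among genes brighter than the median the ERK list's median was 0.11, at percentile 81.3, and it no longer stood apart. EGF receptor family genes had a median of 0.54, which ranged from 0.33 to 0.70 over the scalings and up to 1.57 over all the alternatives. The feedback inhibitor gene ERRFI1 was 5.04-fold, ERBB3 3.09-fold, EGFR 2.83-fold and ERBB2 2.23-fold higher. As the mean over probes, the log2 difference was 1.22 for ERBB3, 1.01 for EGFR and 0.67, under 2-fold, for ERBB2.

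The matrix protease list stood apart at a median of 0.69, or 1.07 with 3 members at their bound. The collagenase gene MMP1 was 15.6-fold, the urokinase gene PLAU 5.93-fold, CTSL 5.17-fold (1.67 in log2 as the mean over its probes) and TIMP2 3.55-fold higher. With normexp the log2 difference of MMP1 was 2.81 against 3.96. The integrin list had a median of 0.42, with a log2 difference of 3.42 for ITGA5, or 2.72 with normexp. In it ITGB6 was 3.01-fold (under 2-fold with normexp, 0.95), ITGB4 2.54-fold and ITGB5 2.32-fold higher. TGF-beta targets also had a median of 0.42, but not among genes brighter than the median, where it was 0.34 at percentile 96.0 and the list did not stand apart. Metallothionein genes had a median of 1.40, with MT1X 7.52-fold and MT1F 5.56-fold higher. Glucocorticoid-responsive genes had a median of 0.96, with TSC22D3 10.3-fold higher and FKBP5 3.16-fold lower, or under 2-fold with normexp (-0.97). Clock genes had a median of 0.70, with PER1 3.87-fold and BHLHE41 3.18-fold higher, the last under 2-fold with normexp (0.91).

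None of the 32 S phase genes was above 0, and 31 were at least 2-fold lower on the PAF array. CLSPN was 7.22-fold, E2F1 7.05-fold, MCM10 6.32-fold and E2F2 5.10-fold lower, and TK1 alone stayed under 2-fold at 1.84-fold lower. With normexp the log2 difference was -1.57 against -2.85 for CLSPN and -1.71 against -2.66 for MCM10. All 30 mitotic genes were below 0, with a median of -0.95 and 14 at least 2-fold lower. FOXM1, a transcription factor of mitotic genes, was 3.42-fold, AURKB 2.64-fold, CDC20 2.59-fold and CCNA2 2.51-fold lower. All 25 ribosome biogenesis genes were below 0, and 20 were at least 2-fold lower, among them RRS1 (5.21-fold), BOP1 (4.62-fold), UTP20 (4.59-fold) and NOP2 (4.36-fold). Another probe of RRP12, a member of that list, was higher (1.05 against -1.60). The medians of these 3 lists lay below those of all 10000 random lists. The 36 cytosolic ribosomal protein genes, in contrast, had a median of -0.08, whose sign changed with the scaling, and none was 2-fold apart.

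**Figure D3:**
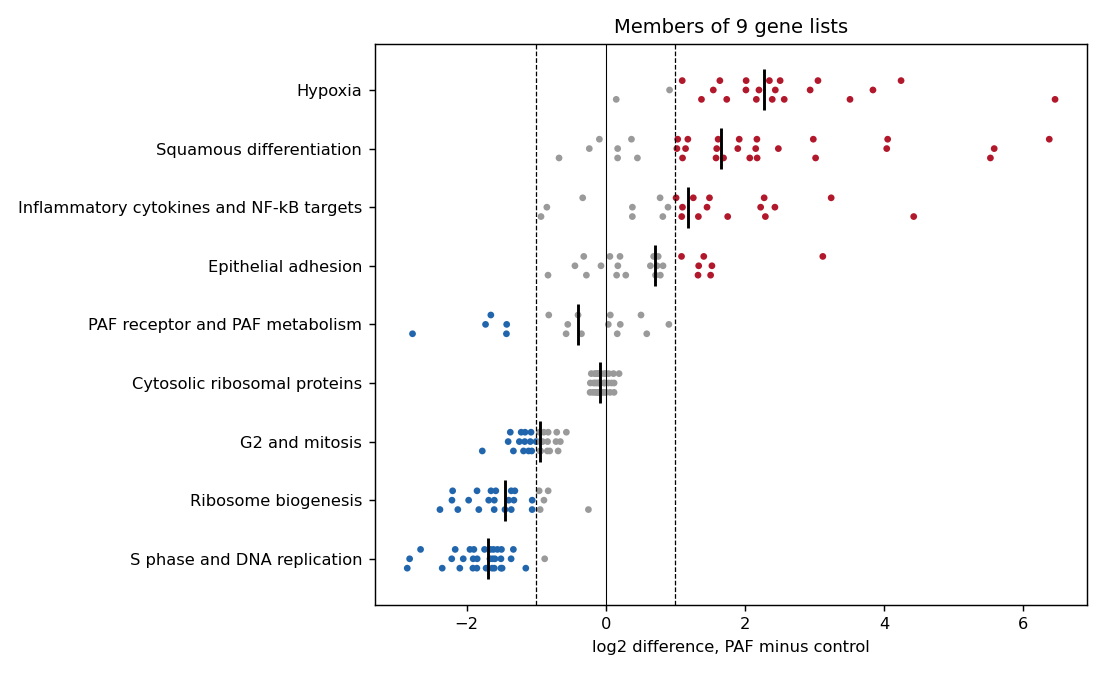
Each point is a measured gene of the named list at its log2 difference, PAF minus control (red at least 2-fold higher, blue at least 2-fold lower), black bars are list medians and dashed lines mark 2-fold. All 22 hypoxia genes lie above 0 (21 with centring on spike-ins), and all 32 S phase, 30 mitotic and 25 ribosome biogenesis genes lie below 0.

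The remaining lower lists were of stress responses. ATF4 targets had a median of -0.69, with 10 of 23 genes at least 2-fold lower and 4 at least 2-fold higher. In that list PSAT1 was 6.72-fold lower, while CHAC1 was 11.0-fold, VLDLR 4.13-fold and DDIT4 3.94-fold higher. NRF2 targets had a median of -0.79. AKR1B10 was 4.49-fold and AKR1C3 3.26-fold lower, and ABCC3 3.27-fold higher. Heat shock genes had a median of -0.78, with HSPH1 3.30-fold and HSPA8 3.28-fold lower and the inducible HSPA6 4.43-fold higher.

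The list of the receptor and metabolism of platelet-activating factor, whose usual abbreviation is PAF, did not stand apart (median -0.40, percentile 9.85). PTAFR, the receptor gene, gave different values at its probes. The probe brighter by the mean of both arrays (chromosome 1, 28520359 to 28520418) had signals of 2080 in the control and 2158 with PAF. It was 1.12-fold higher, a direction that turned with centring on spike-ins. The other probe (28476506 to 28476565) had signals of 533 and 3721, 7.54-fold higher, and was the brighter one on the PAF array. The phospholipase A2 gene PLA2G4C was 6.85-fold lower at its brighter probe and 1.47-fold higher at its dimmer one. Its log2 difference was -1.11 as the mean over probes and -2.15 with normexp, against -2.78. CHPT1 was 3.31-fold, PLA2G4A 3.14-fold and FAR1, of ether lipid synthesis, 2.69-fold lower, PLA2G4A falling under 2-fold with normexp (-0.96).

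The other lists did not stand apart. Their medians were 0.17 for the interferon response, 0.11 for antigen presentation, 0.21 for collagens and basement membrane, 0.22 for YAP targets, 0.12 for Notch targets and -0.24 for WNT targets. They were 0.01 for p53 targets, which stood apart at 0.47 among genes brighter than the median. Of all 21 p53 targets 11 were above 0, with TP53INP1 11.2-fold and CDKN1A 5.12-fold higher and TIGAR 4.02-fold lower. With normexp the log2 difference was 2.41 against 3.49 for TP53INP1, 1.28 against 2.36 for CDKN1A and -1.05 against -2.01 for TIGAR. The medians were 0.11 for apoptosis regulators, -0.26 for cholesterol synthesis, -0.57 for fatty acid synthesis and -0.09 for fatty acid oxidation. Endoplasmic reticulum chaperones had a median of -0.14, replication-dependent histones one of -0.03 and housekeeping genes one of -0.07. The markers of other cell types lay within the random lists too, at 0.45 for fibroblasts, 0.59 for leukocytes, 0.39 for endothelium and 0.10 for erythroid cells and platelets. The leukocyte list stood apart as higher with no filter on dim probes (0.67) and with the mean over a gene's probes (0.59, percentile 97.6). The number of measured genes in these 4 lists was 5, 6, 3 and 5. The signs of the medians for antigen presentation, Notch targets, p53 targets, apoptosis, fatty acid oxidation, chaperones, histones, housekeeping genes and blood markers changed with the scaling.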

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

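Probes without a gene symbol, such as those for long intergenic RNAs, enter none of the gene counts, and a signal in them was therefore looked for separately. Of 8082 such probes well above background on both arrays, 559 were at least 2-fold higher on the PAF array and 475 at least 2-fold lower. Their median difference was -0.05, against -0.12 over named genes. Of the 3621 with long intergenic RNA names, 233 were higher and 212 lower. These differences have no replicate check.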

How the results depend on the processing

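No paired analysis was possible because each group has 1 array and no test was made, and for the same reason no array could be left out. Centring on spike-ins and on the gene median were chosen after seeing the data. In 11 comparisons of a count with an alternative, the count moved by more than 1.5 times. Genes at least 4-fold lower numbered 128, and 75 with centring on probes well above background, 54 with normexp, 267 with no filter on dim probes, 203 with centring on spike-ins and 82 with centring on the gene median. Genes at least 4-fold higher numbered 253 with normexp, against 412. Keeping only genes brighter than the median, which leaves 7410 genes, gave 588 higher and 954 lower at 2-fold, and 137 and 60 at 4-fold. Probes above background on the control array alone numbered 3630 with the looser flag, against 1634. Apart from those due to fewer or more genes tested, the changes with the centrings come from moving all genes against a fixed threshold. For the changes with normexp and with the looser flag, the cause was not tested. The centrings move every gene by the same amount, less than 0.38, the SD between probes of a gene, and no spot was saturated, so the 3 centrings and leaving out saturated probes tested neither the place of a list among random lists nor moves of single genes past that SD. Under the others, list medians stayed higher, lower or neither in 383 comparisons, lost a side in 9 and gained a side in 9. The 383 include lists without a side under either setting, and 21 of the 45 lists had none in the main values. The respiratory chain list accounts for 6 of the 9 losses, and the ERK, TGF-beta and prostanoid lists, among genes brighter than the median, for the others. The gains are fatty acid synthesis in 3, the interferon response and leukocyte markers in 2 each, and p53 targets and antigen presentation in 1 each. The hypoxia median ranged from 2.10 to 2.45 over the scalings, squamous differentiation from 1.48 to 1.81 and S phase from -1.86 to -1.49. Without those 4 alternatives, no value of the 186 named genes that was at least 2-fold apart changed sign. Values moved by less than 0.38 in 1356 comparisons and by more in 61, 46 of them with normexp and 15 with the mean over probes. Of the 1356, 115 come from keeping only brighter genes, which leaves each value unchanged. Another 186 come from dropping the filter, which keeps a value unless another probe is brighter. A further 186 come from the authors' table, nearly equal to the processed signal. These comparisons could hardly move. Signal over background limits what was seen: 20979 genes have probes, and 14821 were well above background on both arrays.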

Other observations

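Gene families chosen after the lists had been seen add to the picture of growth genes. Mitochondrial ribosomal protein genes had a median of -0.78, with 69 to 77 of 77 genes lower on the PAF array, depending on the scaling. Proteasome subunit genes had a median of -0.76, with 36 or 37 of 37 lower, and all 21 nucleoporin genes were lower under each scaling (median -0.81). The chaperonin CCT genes had a median of -1.13, with CCT5 3.12-fold lower and CCT6B, the exception, 3.19-fold higher. RNA polymerase I and III subunit genes had a median of -1.13 and cytosolic aminoacyl-tRNA synthetase genes one of -0.87. Mitochondrial carrier genes had a median of -0.49. The directions of these medians held under all the scalings tried.

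Among families with higher signals, the CEACAM genes had a median of 3.67. CEACAM7 was 13.3-fold and CEACAM6 12.1-fold higher beside CEACAM1 and CEACAM5, while CEACAM19 was 1.38-fold lower. Of 35 keratin genes 32 were above 0 (24 to 33 over the scalings) and 14 at least 2-fold higher. Claudin genes had a median of 1.04, led by CLDN3 (5.25-fold). Mucin genes had one of 0.46, with MUC16 9.63-fold higher, cathepsins one of 0.61, SERPINB genes one of 0.52 and S100A genes one of 0.41. Kallikreins (0.27) and the KDM histone demethylases (0.17) lay within the random lists, although KDM7A was 13.6-fold higher. Annexins (0.13), tetraspanins (-0.05) and ZNF genes (-0.08) did too, with signs that changed with the scaling.

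In the paragraphs that follow, the tests of epithelial adhesion genes, of the number of cultures, and of GC content on the mitotic and ribosome biogenesis lists were chosen only after the result was seen. The hypoxia list was higher as a whole, at 2.28. Its median was 2.40 after loess removed the trend of the difference with signal and 2.28 after the trend with probe GC content was removed, and 1.88 in the lowest of 4 equal parts of the array. These values argue against signal trend, probe GC content and spot position as its cause. A culture that was denser or had less oxygen could give the same pattern. With 1 culture per group this cannot be told apart from an effect of PAF.

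The S phase list kept a median of -1.56 after loess and -1.67 after the GC trend was removed. The corresponding medians were -0.82 and -0.92 for the mitotic list and -1.36 and -1.40 for ribosome biogenesis. These values argue against signal trend and probe GC content as the whole cause of the lower signals. A share of non-epithelial cells large enough to lower these genes would also lower epithelial adhesion genes, if the epithelial cells expressed them as before. The median of the adhesion genes was 0.70. Squamous differentiation genes were higher too (1.65), and a rise of epithelial genes could hide such a share. The adhesion genes therefore do not exclude a share of non-epithelial cells. VIM was above background on the PAF array alone, at least 3.89-fold higher. All 6 measured leukocyte markers, of 16 in the list, were above 0 (median 0.59), with CSF1R 3.85-fold and CD14 2.11-fold higher. Another 2 members, at their bound, were higher as well. The list lay within the random lists, at percentile 96.0. It stood apart as higher with no filter on dim probes (percentile 99.4) and with the mean over a gene's probes (97.6). The labels name only KYSE510 cells on both arrays, but they do not measure what the cultures held. These few markers neither show nor exclude leukocytes as a source of the inflammatory signal. Cultures that differed in density also stay open.

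The squamous differentiation list had a median of 1.67 after the GC trend was removed and of 1.15 in the lowest of those parts of the array, so neither probe GC content nor spot position accounts for it. An effect of PAF and other differences between the cultures stay open.

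Hypotheses on the hypoxia and growth genes were formed after those lists and MXD1 had been seen. They were tested on genes in none of the 45 lists, chosen before their values in the test were seen. Among these, CCT2, CCT3, EIF4A1, EIF4E, KDM4B and ZNF395 also belong to gene families examined separately, whose values may have been seen earlier. Of 14 further HIF targets, 13 were measured, and their median was 1.37, with 11 above 0 and WSB1 4.69-fold higher. This is consistent with higher HIF output in the PAF culture, although HIF1A mRNA itself was 1.31-fold lower. Of 24 further genes known to be activated by MYC, all were below 0, with a median of -1.18 and SRM 4.62-fold lower. Lower MYC output may therefore go with the lower growth genes. MYC mRNA gave no direction, at -0.33 at its brighter probe and 0.11 at its other one, and MXD1, which encodes a competitor of MYC, was 13.6-fold higher. Slower growth for any other reason could lower the same genes, and the list does not separate the 2 readings.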
